A study of Mus musculus with 6 samples.

How the data were processed

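Livers of 10-week-old mice of 2 groups were profiled by RNA sequencing, with 3 libraries per group and 6 in all. The control group, called Ctl here, carried the Albumin-Cre transgene, which expresses Cre recombinase in hepatocytes. The Li-KO group was a liver-specific knockout of Klf15, a Kruppel-like zinc finger transcription factor. Per the labels' protocols, total RNA was isolated from liver on columns and libraries were made with a stranded total RNA kit, so that transcripts without a poly(A) tail and unspliced transcripts can be in the counts. The labels number the libraries 0, 1 and 2 in each group. They do not say which exon was removed, the sex of the mice, the time of day or the feeding state. Each library was taken as 1 replicate. The labels do not state that the libraries of a group come from separate mice, so p-values measure the spread between these libraries.

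Per the submitters' processing notes, reads were aligned with STAR to mm10 and processed with Cufflinks and Cuffdiff. Versions, options, the gene annotation and the strand setting are not given in the sources used here. The deposited table has 1 row per gene and library with 48432 genes. Its raw fragment column holds estimated counts that are not normalized, per the file headers, and 3.29% of the values are not whole numbers. Its FPKM column holds fragments scaled to gene length and library depth after the scaling of Cuffdiff between libraries, per the file headers. The condition names of the table, WT and KO, were matched to Ctl and Li-KO through the titles and replicate numbers of the samples, and 0 columns of per-sample values were left without a sample. A status column marks bundles of overlapping genes that Cuffdiff skipped because they held too many fragments. All genes of such a bundle are listed at 0, abundant ones and those that share a bundle with an abundant gene. They were 77 genes, with 51 skipped in all 6 libraries (Alb, Apob and Apoe among them), 25 skipped in the 3 Ctl libraries only (16 of them Mup genes) and 1, Gc, skipped in the 3 Li-KO libraries only. Skipped genes were left out of the tests and the library totals. Another 45 genes with a failed FPKM estimate in some library kept their raw fragments and stayed in.

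Estimated counts were rounded to whole numbers. Gene IDs were matched to symbols without their version number, with 48051 matched and 381 not matched. Gene type, position, exonic length and transcript sequence came from GENCODE release M21 on the mm10 assembly. Genes with too few counts were removed with the filterByExpr function of edgeR 4.0.16 at its defaults (minimum count 10, minimum total 15), which left 16533 genes. Counts were scaled by TMM and given as CPM, counts relative to the scaled library total. Li-KO was compared with Ctl over the 6 libraries by the two-sided quasi-likelihood test of edgeR with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. The standard error of a log2 fold change was computed from the fold change and its F statistic. Tools were R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

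Before the data were examined, 39 gene lists, the rule for named genes, the design and most alternatives were fixed. Lists with at least 5 measured members (37 lists) were tested with camera of limma on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists. Camera was run again with an estimated correlation, and fry was run as another list test. The lists covered cytochrome P450 families 1 to 3, other phase I enzymes, phase II conjugating enzymes, drug and organic ion transporters, bile acid synthesis, nuclear receptors and liver transcription factors, amino acid catabolism, the urea cycle, gluconeogenesis, lipogenesis and glycolysis, cholesterol synthesis, fatty acid oxidation and ketogenesis, major urinary proteins, clock genes, male-biased and female-biased liver genes, the acute phase, interferon and stress responses, NRF2 and glucocorticoid receptor targets, the Kruppel-like factor family, pericentral and periportal genes, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, nuclear-retained and non-polyadenylated RNAs, histones, the cell cycle, and markers of hepatocytes, Kupffer cells, sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes, lymphocytes, neutrophils, erythroid cells and tissue carried over from other organs. Genes within 10 Mb and within 1 Mb of Klf15 were tested in the same way.

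The genes named were Klf15, then the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap and whose mean CPM was at least 1. Symbols starting with Gm, LOC or Rn and a digit, with Mir or with Snor, or ending in Rik were left out of these. Up to 4 called members per list with the smallest p were named, or up to 2 of the highest CPM where none was called. The 5 genes of highest mean CPM completed the set, not all of which is given in the text. Genes named outside this rule were chosen after their values were seen and are marked as such, except the genes beside Klf15, which position chose.

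Depth was 30716766 to 43375775 fragments per library. A count of 3 in a library corresponds to 0.0701 to 0.0996 CPM. Intervals on ratios of low counts cover counting error only. In simulated data with the means, library sizes and dispersions of these libraries and 200 changed genes, edgeR recovered 2% of 50 genes changed 1.5-fold, 36% of 50 changed 2-fold, 82% of 50 changed 4-fold and 86% of 50 changed 8-fold, and 7.2% of its calls were unchanged genes. DESeq2 recovered 52% of the genes changed 2-fold, and 25.6% of its calls were unchanged genes. More than 200 genes were called in the data, so these shares may not hold for the real comparison. No library of a group was a duplicate of another, since chi-square per degree of freedom between libraries of a group was 40.6 to 124.6.

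Alternatives fixed before the data were examined were RLE scaling, total counts, totals without the 20 genes of highest mean count, no low-count filter, a mean count of 50 or more, DESeq2, limma-voom, the robust fit of edgeR, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, a test against a fold of 1.5, and leaving out each library in turn. Keeping the skipped genes at 0 and removing the genes with a failed FPKM estimate were added after the data were seen.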

Results

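The series compared the liver transcriptomes of 10-week-old Albumin-Cre control mice (Ctl, n = 3 libraries) and mice that lack Klf15 in the liver (Li-KO, n = 3 libraries). It addresses which liver transcripts depend on hepatic Klf15, a transcription factor. The total count was 42745995, 35711578 and 38796320 fragments in Ctl replicates 0, 1 and 2, and 30716766, 31774646 and 43375775 in Li-KO replicates 0, 1 and 2. The 20 most abundant genes that were measured took 8.33% to 9.74% of the counts. Levels are CPM, given as mean ± SD over the 3 libraries of a group, and log2 fold changes are Li-KO minus Ctl with their SE. Adjusted p-values are from edgeR unless camera is named.

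Klf15 (ENSMUSG00000030087.11, chromosome 6, 90462576 to 90475238, plus strand, mm10) was lower in each Li-KO library than in each Ctl library. Its level was 345, 174 and 196 CPM in Ctl replicates 0, 1 and 2, and 54.3, 41.6 and 51.8 CPM in Li-KO replicates 0, 1 and 2. The group means were 238 ± 93.3 CPM and 49.2 ± 6.75 CPM, a 4.84-fold decrease with a log2 fold change of -2.28 ± 0.26 and an adjusted p of 0.00275. The counts cover all exons of the gene, and the labels do not name the exon that was removed.

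Among 16533 genes tested, 1010 were higher and 976 lower in Li-KO liver, together 12.01% of the genes. Of these, 294 were higher and 400 lower by 2-fold or more. The 3 values of each group did not overlap in 1985 of the 1986 changed genes, and in 35.21% of all genes tested, where chance gives 10%. A call nearly requires such a separation, so the first count adds no support to the calls. Genes of the same libraries are correlated, so the share of all genes can also stray from 10% by chance. The median log2 fold change of all genes was -0.01. The first principal component of the 500 most variable genes held 59.32% of the variance and separated the groups, with scores of -32.3 to -21.6 in Ctl and 18.2 to 39.3 in Li-KO. The second held 16.19% and set Li-KO replicate 0, at 27.0, apart from Li-KO replicates 1 and 2, at -17.2 and -18.1. Counts of changed genes depended on single libraries. Leaving out Ctl replicate 1 gave 198 higher and 234 lower genes, leaving out Ctl replicate 2 gave 255 and 387, and leaving out Li-KO replicate 1 gave 226 and 250. Leaving out Ctl replicate 0 gave 704 and 602, leaving out Li-KO replicate 0 gave 675 and 554, and leaving out Li-KO replicate 2 gave 1102 and 1447. Of 109 called genes besides Klf15 that the rule for named genes chose, 60 kept their call in each of these 6 fits. Of these 60, Nptx1, Gapdhs, Pde6c, Capn8, Aldh1a7 and Mup6 lost it with limma on FPKM of all genes above 0. A fit without a library has fewer samples, so a call can end while the fold change holds. Over the 6 fits that left out a library, the log2 fold change of Asgr2 stayed at 0.55 to 0.63, while that of Rasal1 spread from 3.16 to 6.33.

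The largest increases were in genes with little or no expression in Ctl liver. Sall4, a zinc finger transcription factor of embryonic cells, had 0, 0 and 5 counts in the Ctl libraries and 76, 58 and 161 in the Li-KO libraries, with an adjusted p of 0.00775. Nptx1, a neuronal pentraxin, rose from 0.129 ± 0.055 to 4.73 ± 2.33 CPM, and Gapdhs, the sperm form of glyceraldehyde-3-phosphate dehydrogenase, from 0.058 ± 0.060 to 2.07 ± 0.960 CPM. Dnah5, an axonemal dynein heavy chain, rose from 0.542 ± 0.067 to 10.4 ± 3.13 CPM (log2 fold change 4.25 ± 0.30, adjusted p = 0.000495). Rasl10b rose from 0.241 ± 0.047 to 4.86 ± 1.79 CPM, Sybu from 0.311 ± 0.188 to 6.47 ± 2.39 CPM and Pde6c, a cone photoreceptor phosphodiesterase, from 0.213 ± 0.045 to 5.05 ± 3.67 CPM. Syt14, a synaptotagmin, rose from 0.170 ± 0.148 to 2.64 ± 1.37 CPM, and Sult1e1, the estrogen sulfotransferase, from 0.378 ± 0.400 to 7.54 ± 5.88 CPM. Shisa8 had 7, 0 and 3 counts in Ctl and 12, 75 and 500 in Li-KO, and Rasal1 8, 2 and 0 in Ctl and 180, 29 and 25 in Li-KO. Meg3 (ENSMUSG00000021268.17), an imprinted long non-coding RNA on chromosome 12, was the only one of the 12 with more than 10 CPM in Li-KO besides Dnah5. It rose from 5.74 ± 3.42 to 85.7 ± 29.1 CPM, a log2 fold change of 3.90 ± 0.48 and an adjusted p of 0.00367. The calls of Shisa8, Rasal1, Syt14 and Sult1e1 ended when Ctl replicate 1 was left out, as in some of the other fits without a library, with adjusted p up to 0.108, 0.129, 0.0760 and 0.0731.

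The 12 largest decreases included 3 Slc carriers. Slc16a5, of the monocarboxylate transporter family, had 1209, 252 and 494 counts in the Ctl libraries and 0, 0 and 1 in the Li-KO libraries, a ratio of 1732 with a counting interval of 310.6 to 68460 (95%, exact binomial). Slc13a2, a sodium-dependent dicarboxylate transporter, had 307, 188 and 107 counts against 0, 0 and 2, a ratio of 267 with an interval of 73.5 to 2208. Slc25a34, a mitochondrial carrier, had 423, 195 and 177 counts against 0, 1 and 3. In the fits that left out a library, the log2 fold change was -12.2 to -9.57 for Slc16a5 and -10.5 to -7.36 for Slc13a2. Sucnr1, the succinate receptor, fell from 25.1 ± 7.78 to 0.476 ± 0.034 CPM (log2 fold change -5.71 ± 0.29, adjusted p = 0.000159), the smallest adjusted p of the 12. Ces1b, a carboxylesterase, fell from 76.2 ± 32.9 to 1.38 ± 0.594 CPM and Rgs16, a regulator of G protein signalling, from 33.4 ± 15.6 to 0.786 ± 0.636 CPM. Epop fell from 5.93 ± 1.58 to 0.151 ± 0.075 CPM and Capn8, a calpain, from 12.02 ± 6.94 to 0.394 ± 0.355 CPM. Cyp4a12b, a fatty acid omega-hydroxylase, fell from 110 ± 25.3 to 1.74 ± 1.56 CPM and Cyp4a10 from 209 ± 103 to 5.19 ± 7.68 CPM. The pseudogene Cyp2c53-ps fell from 3.54 ± 1.996 to 0.115 ± 0.151 CPM and Cyp2c69 from 2.03 ± 1.52 to 0.062 ± 0.052 CPM. The calls of Cyp4a10, Cyp2c53-ps and Cyp2c69 ended without Li-KO replicate 1, with adjusted p of up to 0.0981, 0.0506 and 0.0547 over the fits that left out a library. The Cyp4a, Cyp2c and Ces1 genes have near-identical neighbours, and how fragments that match several copies were assigned is not given in the sources used here, so their values are uncertain.

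**Figure D1:**
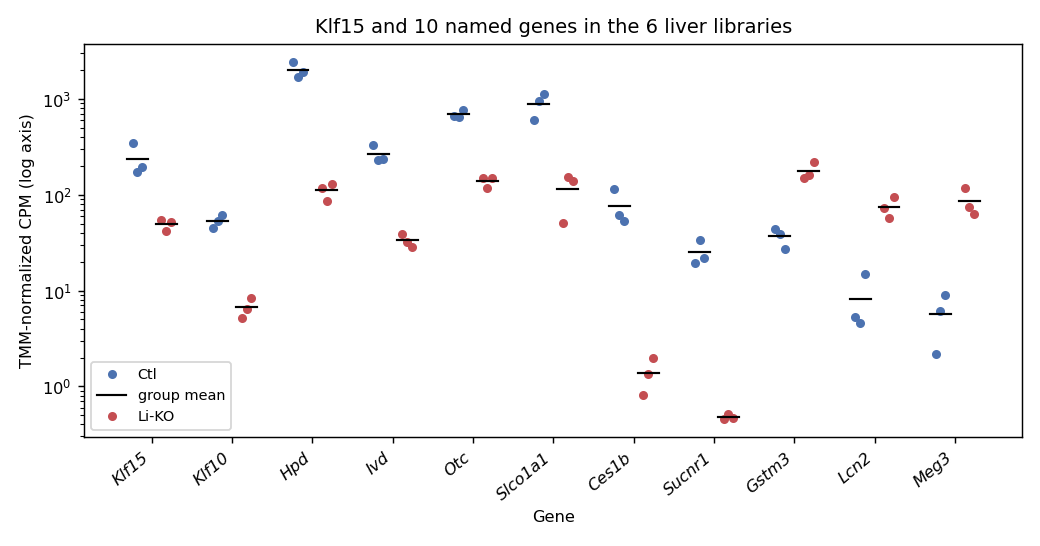
TMM-normalized CPM on a log axis of Klf15 and 10 named genes in the 6 libraries, with Ctl in blue, Li-KO in red and group means as bars. Klf15 sits at 174 to 345 CPM in Ctl and at 41.6 to 54.3 CPM in Li-KO, and the groups do not overlap for any gene shown.

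Genes of amino acid breakdown fell more often than they rose. Of 58 measured genes of amino acid catabolism, 20 fell and 6 rose (24 and 7 adjusted over the list alone). Hpd (ENSMUSG00000029445.13), which acts in tyrosine breakdown, fell from 2030 ± 372 to 111 ± 23.3 CPM, a log2 fold change of -4.19 ± 0.23 with an adjusted p of 0.00024. Ivd, which acts on leucine, fell from 266 ± 55.6 to 33.3 ± 5.57 CPM. Acadsb, a dehydrogenase of branched-chain acyl groups, fell from 320.9 ± 21.5 to 121 ± 4.48 CPM, and Dhtkd1, which acts in lysine and tryptophan breakdown, from 126 ± 28.9 to 14.1 ± 4.52 CPM. Tdo2, the first enzyme of tryptophan breakdown and also a hepatocyte marker, fell from 2325 ± 697 to 526 ± 27.7 CPM. Ftcd, of histidine breakdown, moved the other way, from 334 ± 77.7 to 795 ± 112 CPM. By camera the list was lower (adjusted p = 0.0155), and the adjusted p was 0.946 with an estimated correlation. Without Ctl replicate 0 the adjusted p was 0.181. Of the 9 other splits of the 6 libraries into 3 and 3, 2 gave a smaller adjusted p than the real one, down to 0.0009.

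The urea cycle and gluconeogenesis held changes in both directions. Of 7 measured urea cycle genes, 1 fell and 2 rose (1 and 3 adjusted over the list alone), with a camera adjusted p of 0.425. Otc, ornithine transcarbamylase, fell from 693 ± 66.6 to 139 ± 18.96 CPM (log2 fold change -2.32 ± 0.16, adjusted p = 0.000495). Asl, argininosuccinate lyase, rose from 880 ± 296 to 1655 ± 141 CPM, and the carrier Slc25a13 from 402 ± 27.9 to 567 ± 53.0 CPM. Cps1 was skipped in the table. Of 14 measured gluconeogenesis genes, 2 fell and 2 rose (2 and 4 adjusted over the list alone, camera adjusted p = 0.448). Gpt, alanine aminotransferase, fell from 361 ± 55.6 to 209 ± 12.7 CPM and Pcx, pyruvate carboxylase, from 687 ± 42.3 to 481 ± 40.3 CPM. Fbp1, fructose-1,6-bisphosphatase, rose from 1066 ± 142 to 2024 ± 316 CPM and Pdk4, a pyruvate dehydrogenase kinase, from 9.28 ± 0.226 to 15.1 ± 1.19 CPM. Pck1, chosen after its values were seen, the rate-limiting enzyme of gluconeogenesis, was at 6436 CPM in Ctl replicate 0 against 1840 and 2963 in Ctl replicates 1 and 2, and did not pass (adjusted p = 0.603). The calls of Asl, Slc25a13, Gpt, Pcx, Fbp1 and Pdk4 all ended without Li-KO replicate 1, with adjusted p of 0.0646 to 0.144 as the highest of the fits that left out a library.

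Enzymes and transporters of drug metabolism changed in both directions. Of 39 measured genes of cytochrome P450 families 1 to 3, 6 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.576). Cyp2c70, a bile acid hydroxylase in mice, fell from 789 ± 58.0 to 361 ± 71.2 CPM, a log2 fold change of -1.13 ± 0.17 with an adjusted p of 0.00761. Cyp2a5 fell from 1241 ± 93.9 to 618 ± 181 CPM, and the low-level Cyp2c40 from 4.22 ± 1.96 to 0.275 ± 0.316 CPM. The member that rose was Cyp2b9, chosen after its value was seen, with 0.288, 0.404 and 1.86 CPM in Ctl and 0.935, 15.0 and 229 CPM in Li-KO replicates 0, 1 and 2. Of 41 other phase I enzymes, 3 fell and 4 rose (5 and 7 adjusted over the list alone, camera adjusted p = 0.734). Ces1b and Ces3b, at 578 ± 120 CPM in Ctl and 325 ± 43.7 CPM in Li-KO, fell. Ces1g rose from 179 ± 41.8 to 590.1 ± 166 CPM and the aldehyde dehydrogenase Aldh1a7 from 201 ± 28.0 to 432 ± 89.0 CPM. Of 53 phase II conjugating enzymes, 6 fell and 6 rose (9 and 9 adjusted over the list alone, camera adjusted p = 0.732). The glutathione transferases Gstm7, at 43.2 ± 9.10 CPM in Ctl and 5.52 ± 1.08 CPM in Li-KO, Gstk1, at 88.8 ± 14.5 and 25.1 ± 4.09 CPM, and Gstz1, at 653 ± 34.1 and 267 ± 26.3 CPM, fell. Gstm3 rose from 36.8 ± 8.53 to 176 ± 38.0 CPM, a log2 fold change of 2.26 ± 0.22 with an adjusted p of 0.00118. Calls of Cyp2a5, Cyp2c40 and Ces3b ended without Ctl replicate 2 and without Li-KO replicate 1, with adjusted p up to 0.0934, 0.0752 and 0.0917.

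Of 31 measured hepatic drug and organic ion transporters, 7 fell and 4 rose (9 and 6 adjusted over the list alone, camera adjusted p = 0.758). Slco1a1, an uptake carrier of organic anions, fell from 890.2 ± 266 to 114 ± 54.7 CPM, a log2 fold change of -2.97 ± 0.41 with an adjusted p of 0.00603. Slc10a2, the apical sodium-dependent bile acid transporter, fell from 77.3 ± 22.2 to 16.2 ± 5.81 CPM and Slc22a18 from 92.5 ± 15.8 to 37.3 ± 7.16 CPM. Abcb1a, a multidrug efflux pump, rose from 10.8 ± 1.10 to 41.0 ± 18.3 CPM, and its call ended without Ctl replicate 1 or 2, with an adjusted p of up to 0.0521. Of 20 genes of bile acid synthesis and conjugation, 1 (Cyp2c70) fell and 2 rose (1 and 2 adjusted over the list alone, camera adjusted p = 0.734). Amacr, a racemase of the bile acid side chain, rose from 121 ± 11.1 to 190.4 ± 20.7 CPM and Acot8, a peroxisomal thioesterase, from 10.5 ± 1.17 to 16.3 ± 0.604 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, chosen after its values were seen, had a log2 fold change of -0.50 and an adjusted p of 0.391. Of 44 nuclear receptors and liver transcription factors, 6 fell and 4 rose (8 and 5 adjusted over the list alone, camera adjusted p = 0.425). Esrra, an estrogen-related receptor, rose from 39.015 ± 2.16 to 78.1 ± 10.2 CPM and Rarb, a retinoic acid receptor, from 7.43 ± 0.889 to 13.1 ± 1.65 CPM. Nr2f2 fell from 55.8 ± 6.69 to 33.0 ± 4.29 CPM and the coactivator Ppargc1b from 16.0 ± 3.38 to 7.99 ± 1.18 CPM. Of 30 NRF2 targets, 5 fell and 3 rose (8 and 5 adjusted over the list alone, camera adjusted p = 0.734). Gstm3 rose, as did G6pdx, from 6.02 ± 1.10 to 12.6 ± 1.14 CPM, while Gsta4 fell from 103 ± 18.0 to 43.3 ± 8.77 CPM. The calls of Amacr, Acot8, Rarb, Nr2f2, Ppargc1b and G6pdx ended without Ctl replicate 1, with adjusted p of 0.0633 to 0.106 as the highest of the fits that left out a library.

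Lipid genes changed in both directions, except in cholesterol synthesis. Of 24 measured cholesterol synthesis genes, 3 rose and 0 fell (11 and 0 adjusted over the list alone). Among them, Hmgcs1 rose from 161 ± 39.3 to 299 ± 69.1 CPM and Fdps from 72.4 ± 10.0 to 124 ± 35.1 CPM. Camera put the list higher (adjusted p = 0.0123), with an adjusted p of 0.946 with an estimated correlation and of 0.0709 without Li-KO replicate 1. Of 27 lipogenesis and glycolysis genes, 6 fell and 5 rose (7 and 5 adjusted over the list alone, camera adjusted p = 0.932). Pklr, liver pyruvate kinase, fell from 349 ± 93.6 to 73.4 ± 24.1 CPM and Me1, malic enzyme, from 132 ± 44.0 to 26.6 ± 13.2 CPM. Acaca, acetyl-CoA carboxylase, fell from 157 ± 16.6 to 81.6 ± 11.05 CPM, while Gpam, the first enzyme of glycerolipid synthesis, rose from 347 ± 30.97 to 720.1 ± 139.6 CPM. Of 45 genes of fatty acid oxidation and ketogenesis, 5 fell and 7 rose (8 and 14 adjusted over the list alone, camera adjusted p = 0.425). Cyp4a genes were 4 of the 5 that fell, Cyp4a32 from 19.6 ± 2.15 to 0.657 ± 0.525 CPM among them. Plin2, a lipid droplet coat protein, rose from 248 ± 46.8 to 594 ± 85.0 CPM and the transcription factor Creb3l3 from 295 ± 28.9 to 544 ± 40.7 CPM. The calls of Hmgcs1 and Fdps ended without Ctl replicate 0, 1 or 2 or without Li-KO replicate 1, with adjusted p up to 0.134 and 0.156, and that of Gpam ended without Li-KO replicate 1 (adjusted p = 0.0507).

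Sex-biased liver genes were also affected. Of 27 measured male-biased genes, 7 fell and 0 rose (9 and 2 adjusted over the list alone). They included Cyp4a12b and Slco1a1, Nox4, an NADPH oxidase that fell from 97.7 ± 15.3 to 50.4 ± 9.63 CPM, and Keg1, which fell from 283 ± 32.6 to 146 ± 36.4 CPM. Camera put the list lower (adjusted p = 0.0155), with an adjusted p of 0.946 with an estimated correlation. The camera call ended without Ctl replicate 2 (adjusted p = 0.0699) and without Li-KO replicate 2 (adjusted p = 0.141). It also ended by fry (adjusted p = 0.364) and when skipped genes were kept at 0, which puts false zeros in Ctl (adjusted p = 0.531). Of the 9 other splits, 4 gave a smaller adjusted p than the real one, down to 1.54e-08. Of 22 measured female-biased genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0802). Sult1e1 and Atp6v0d2, a proton pump subunit at 1.53 ± 0.596 CPM in Ctl and 6.24 ± 1.38 CPM in Li-KO, rose, and Cyp2c69 and Cyp2c40 fell. Major urinary proteins were mostly skipped in Ctl. Of the 3 measured, Mup6, at 16.6 ± 10.8 CPM in Ctl and 1.32 ± 0.280 CPM in Li-KO, and Mup5, at 2.998 ± 2.22 and 0.346 ± 0.174 CPM, fell (2 lower and 0 higher, and the same numbers adjusted over the list alone), and the list was too small to test. The calls of Nox4 and Keg1 ended without Ctl replicate 1 or 2, with adjusted p up to 0.0676 and 0.0852, and that of Mup5 without each library except Ctl replicate 0, with adjusted p up to 0.107. Mup6 did not pass with limma-voom. How fragments shared with the skipped Mup genes were assigned is not given in the sources used here, so the values of Mup6 and Mup5 are uncertain.

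Some other Kruppel-like factors fell. Of 18 measured members of the family besides Klf15, the Sp factors included, 8 fell and 0 rose (10 and 0 adjusted over the list alone). Klf10 fell from 53.4 ± 8.25 to 6.67 ± 1.63 CPM, a log2 fold change of -2.997 ± 0.21 with an adjusted p of 0.000495. Klf12 fell from 19.6 ± 3.91 to 9.23 ± 0.873 CPM, Sp4 from 16.6 ± 0.695 to 8.76 ± 1.12 CPM and Klf7 from 22.1 ± 2.21 to 13.4 ± 1.04 CPM. Camera put the family lower (adjusted p = 2.84e-05), with an adjusted p of 0.819 with an estimated correlation, and fry gave an adjusted p of 0.0351. The calls of Sp4 and Klf7 ended without Ctl replicate 1, with adjusted p up to 0.0613 and 0.0917. Of 21 clock genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.281). This was Arntl, a core activator of the clock, at 17.1 ± 6.19 CPM in Ctl and 6.08 ± 2.56 CPM in Li-KO, whose call ended without Ctl replicate 0 or 1 or Li-KO replicate 0 or 1 (adjusted p up to 0.112).

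Acute phase and interferon genes held few changes. Of 30 acute phase genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.732), which was Lcn2, lipocalin 2, at 8.26 ± 5.77 CPM in Ctl and 74.7 ± 18.4 CPM in Li-KO (log2 fold change 3.18 ± 0.44, adjusted p = 0.00603). Of 42 interferon response genes, 1 fell and 1 rose (0 and 0 adjusted over the list alone, camera adjusted p = 0.583). Mx2 fell from 8.57 ± 0.650 to 3.25 ± 1.41 CPM and Irf7 rose from 28.3 ± 2.36 to 55.4 ± 22.2 CPM. Of 31 genes of the unfolded protein and integrated stress response, 4 rose and 2 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.480). The serine synthesis enzyme Psat1 rose from 0.648 ± 0.328 to 4.28 ± 2.13 CPM, asparagine synthetase, Asns, from 6.59 ± 7.05 to 56.4 ± 37.8 CPM and the transcription factor Atf4 from 113 ± 8.87 to 178 ± 35.8 CPM, while Atf5 fell from 70.4 ± 17.9 to 44.0 ± 4.08 CPM. Of 24 glucocorticoid receptor targets, 3 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.480). Without Ctl replicate 0 the list was higher by camera (adjusted p = 0.0427). Over all libraries, camera with an estimated correlation gave an adjusted p of 0.946. The called members were Lcn2, Sult1e1 and Gadd45b, at 0.974 ± 0.406 CPM in Ctl and 5.28 ± 4.14 CPM in Li-KO. The calls of Mx2, Irf7, Psat1, Asns, Atf4, Atf5 and Gadd45b ended without Ctl replicate 1 or 2 or Li-KO replicate 1, with adjusted p of 0.0824 to 0.162 as the highest of the fits that left out a library.

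Many ribosomal protein and respiratory chain genes rose and 0 fell. Of 74 measured nuclear-encoded genes of oxidative phosphorylation, 45 rose and 0 fell (62 and 1 adjusted over the list alone), with a median log2 fold change of 0.52. Atp5g1, a subunit of ATP synthase, rose from 21.1 ± 1.27 to 47.4 ± 2.93 CPM (log2 fold change 1.17 ± 0.12, adjusted p = 0.00165). Ndufv1, of complex I, rose from 168 ± 14.8 to 299.7 ± 8.71 CPM, Ndufs5 from 7.56 ± 1.49 to 17.7 ± 1.17 CPM and Uqcr10, of complex III, from 76.8 ± 11.3 to 143 ± 5.01 CPM. Of 71 cytoplasmic ribosomal protein genes, 27 rose and 0 fell (40 and 2 adjusted over the list alone), with a median log2 fold change of 0.48. Rps21 rose from 21.2 ± 4.44 to 51.2 ± 1.88 CPM, Rps7 from 2.22 ± 0.506 to 7.60 ± 1.09 CPM, Rpl26 from 27.9 ± 5.67 to 58.2 ± 3.78 CPM and Rpl13 from 10.4 ± 2.99 to 24.6 ± 1.31 CPM. Camera put both lists higher, with adjusted p of 2.73e-18 and 8.83e-12, and the adjusted p was 0.819 for both with an estimated correlation. Ribosomal protein genes share sequence with many pseudogenes, so their levels are uncertain. Of the genes encoded by mitochondrial DNA only 3 were measured, none passed (0 higher and 0 lower, and 0 and 0 adjusted over the list alone), and the list was too small to test. Among them mt-Nd2 was at 1.09 ± 0.782 CPM in Ctl and 1.77 ± 0.893 CPM in Li-KO and mt-Nd6 at 0.401 ± 0.114 and 0.204 ± 0.049 CPM. No member of the list was marked as skipped. The others were thus either removed by the low-count filter or absent under the listed symbols, and the reason is not given in the sources used here. These values therefore do not show the level of mitochondrial RNA or whether it changed.

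Of 11 measured nuclear-retained and non-polyadenylated RNAs, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0775). Besides Meg3 they were Rmrp, the RNA of RNase MRP, at 575 ± 223 CPM in Ctl and 1225 ± 208 CPM in Li-KO, and Terc, the telomerase RNA, at 3.63 ± 0.911 and 7.89 ± 2.63 CPM. Of 28 replication-dependent histone genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone, camera adjusted p = 0.232), which was Hist2h2be, from 3.13 ± 0.415 to 1.38 ± 0.097 CPM. Of 34 cell cycle genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.971), which was Rrm2, a ribonucleotide reductase subunit, from 14.4 ± 7.25 to 1.30 ± 0.518 CPM. The calls of Rmrp, Terc and Hist2h2be ended without Ctl replicate 1 or 2 or Li-KO replicate 0 or 1, with adjusted p up to 0.122, 0.143 and 0.0919.

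Zonation genes changed on both sides of the lobule. Of 27 pericentral genes, 4 fell and 2 rose (5 and 3 adjusted over the list alone, camera adjusted p = 0.146). Besides Gstm3, which rose, Slc1a4 fell from 8.64 ± 1.98 to 2.35 ± 0.216 CPM, Notum, a Wnt antagonist, from 31.7 ± 9.29 to 14.4 ± 1.37 CPM and Rgn, regucalcin, from 1236 ± 117 to 594 ± 192 CPM. Of 24 periportal genes, 5 fell and 6 rose (5 and 7 adjusted over the list alone, camera adjusted p = 0.425). Igfbp2, a binding protein of insulin-like growth factors, fell from 406 ± 14.3 to 80.8 ± 34.8 CPM and the transcription factor Sox9 from 14.7 ± 2.64 to 2.82 ± 0.646 CPM. Of 19 measured hepatocyte markers, 2 fell (Hpd and Tdo2) and 1 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.580), and Asgr2, an asialoglycoprotein receptor subunit, rose from 173 ± 9.68 to 260 ± 11.3 CPM. The calls of Notum, Rgn and Asgr2 ended without Ctl replicate 1 and without Li-KO replicate 1, with adjusted p up to 0.0597, 0.108 and 0.0757.

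Most marker lists of other cell types held no called gene. No member passed among 24 Kupffer cell and macrophage markers (camera adjusted p = 0.971), 24 sinusoidal endothelial markers (0.425), 22 lymphocyte markers (0.394), 6 neutrophil markers (0.425) and 6 markers of carried-over tissue (0.338). Adjusted over the list alone, 1 carry-over marker rose and 0 members of the other 4 lists passed. The Kupffer cell marker Clec4f was at 88.9 ± 13.5 CPM in Ctl and 84.8 ± 12.5 CPM in Li-KO, and Slc40a1 at 248 ± 78.2 and 294 ± 95.2 CPM. The endothelial marker Stab2 was at 187 ± 12.8 and 168 ± 38.0 CPM and Ptprb at 347 ± 28.4 and 282 ± 78.3 CPM. The leukocyte marker Ptprc was at 23.3 ± 4.05 and 19.6 ± 6.55 CPM and Igkc at 5.04 ± 1.81 and 6.85 ± 1.52 CPM. Of the neutrophil markers Il1b was at 8.35 ± 3.81 and 3.39 ± 1.68 CPM and Csf3r at 3.02 ± 1.02 and 3.11 ± 0.732 CPM. Among the carry-over markers Plin4 was at 26.5 ± 19.95 and 50.2 ± 13.5 CPM and Cela1 at 10.1 ± 2.58 and 7.14 ± 1.62 CPM. Of 32 stellate cell, fibroblast and matrix markers, 2 fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.816), namely Rgs5, from 83.5 ± 19.6 to 34.7 ± 10.96 CPM, and Hand2, from 7.10 ± 0.799 to 4.03 ± 0.737 CPM. Of 17 cholangiocyte markers, 1 (Sox9) fell and 2 rose (1 and 2 adjusted over the list alone, camera adjusted p = 0.0563), namely Pkhd1, from 29.4 ± 7.31 to 55.0 ± 6.98 CPM, and Slc4a2, from 46.8 ± 2.67 to 75.1 ± 15.9 CPM. No erythroid marker of 12 passed over all genes (3 lower and 0 higher adjusted over the list alone). Camera put the erythroid list lower (adjusted p = 0.0155), with an adjusted p of 0.946 with an estimated correlation and of 0.0685 without Ctl replicate 2. Hbb-bs, a globin, was at 339 ± 18.5 CPM in Ctl and 219 ± 84.5 CPM in Li-KO, and Fech at 253 ± 25.2 and 248 ± 11.9 CPM. The calls of Rgs5, Hand2, Pkhd1 and Slc4a2 ended without Ctl replicate 2 and without Li-KO replicate 1, with adjusted p up to 0.0540, 0.175, 0.0912 and 0.117.

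**Figure D2:**
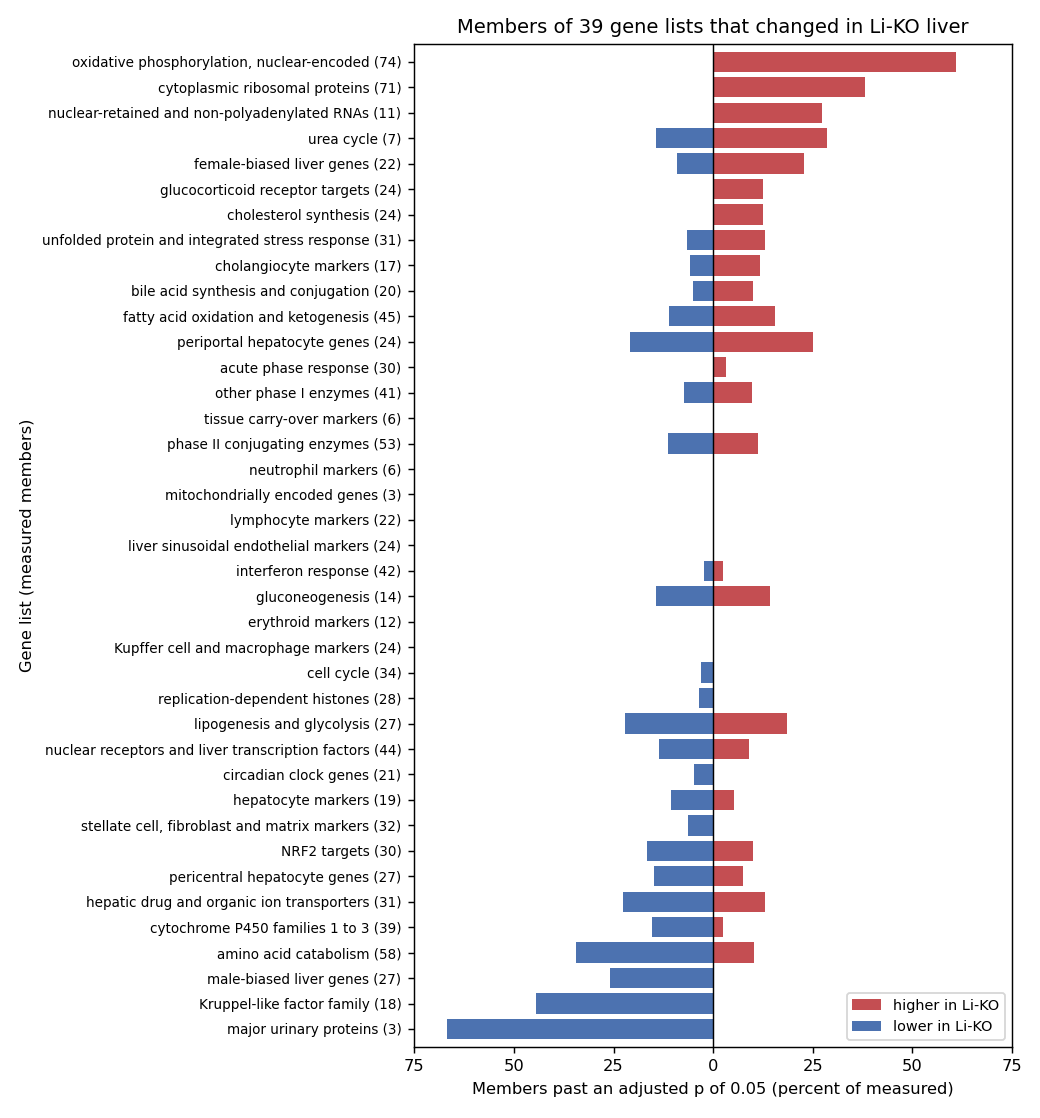
Percent of the measured members of 39 gene lists that were higher (red, right) or lower (blue, left) in Li-KO past an adjusted p of 0.05, with the number measured in parentheses. Oxidative phosphorylation (45 of 74) and ribosomal proteins (27 of 71) lead on the right, and 6 lists of markers of other cells and tissues and the mitochondrially encoded genes have no bar.

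In all, 7 of 37 lists passed camera, 3 higher and 4 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.819. By fry, amino acid catabolism, cholesterol synthesis, male-biased genes and erythroid markers did not pass, with adjusted p of 0.148, 0.218, 0.364 and 0.261. Besides glucocorticoid receptor targets, 9 further lists passed camera in some fit without a library. Among them, the female-biased list passed without Ctl replicate 0 (adjusted p = 0.00708) or Li-KO replicate 0 (0.00439). Cholangiocyte markers passed without Ctl replicate 2 (0.00528), Li-KO replicate 0 (0.0291) or Li-KO replicate 1 (0.0425), sinusoidal endothelial markers without Li-KO replicate 2 (0.0191), lymphocyte markers without Li-KO replicate 1 (0.0425) and neutrophil markers without Ctl replicate 0 (0.0283). The other 4 were fatty acid oxidation and ketogenesis, pericentral genes, nuclear-retained RNAs and histones. The mean and median log2 fold change of a list had opposite signs in 7 tested lists, none of which passed. The median was 0.21 and the mean -0.34 in fatty acid oxidation and ketogenesis, 0.24 and -0.18 in hepatocyte markers, 0.08 and -0.07 in the cell cycle, 0.01 and -0.10 in NRF2 targets and 0.003 and -0.07 in transporters. The median was -0.03 and the mean 0.04 in phase II enzymes, and -0.02 and 0.02 in Kupffer cell markers. Lipogenesis and glycolysis had a median of -0.01 and a mean of -0.10, while camera gave the direction as higher.

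Genes close to Klf15 changed more often than others. Within 1 Mb of its start, 8 of 21 measured genes changed, 38.1%, with 6 higher and 2 lower (two-sided Fisher's exact p = 0.00205 against the other genes tested, 6 and 2 adjusted over the list alone). All of these were chosen by position. On the plus strand just downstream, Gm44421 (chromosome 6, 90478466 to 90479686) rose from 11.6 to 31.7 CPM, and Gm45901 (90486393 to 90519480) and Gm44236 (90513302 to 90513814), which overlap the gene body of Aldh1l1, rose from 0.083 to 3.26 CPM and from 0.643 to 5.75 CPM. Gm44236 also lies within Gm45901 on the same strand. How fragments of overlapping genes were assigned is not given in the sources used here, so the values of these 2 genes are uncertain. Slc41a3 (90604725 to 90646412), of the magnesium transporter family, rose from 3.14 to 25.3 CPM, a log2 fold change of 3.004 ± 0.37 with an adjusted p of 0.00381. Chst13 and Chchd4, both on the minus strand, rose by log2 fold changes of 1.14 and 0.63. Aldh1l1, a folate enzyme on the plus strand between Gm44421 and Slc41a3, fell from 1991 to 1293 CPM, and Iqsec1 had a log2 fold change of -0.64. Camera gave p = 0.0112 for the 21 genes, and p = 0.134 with an estimated correlation. Within 10 Mb, 25 of 181 genes changed, 13.8% (Fisher's exact p = 0.422, camera p = 0.863).

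**Figure D3:**
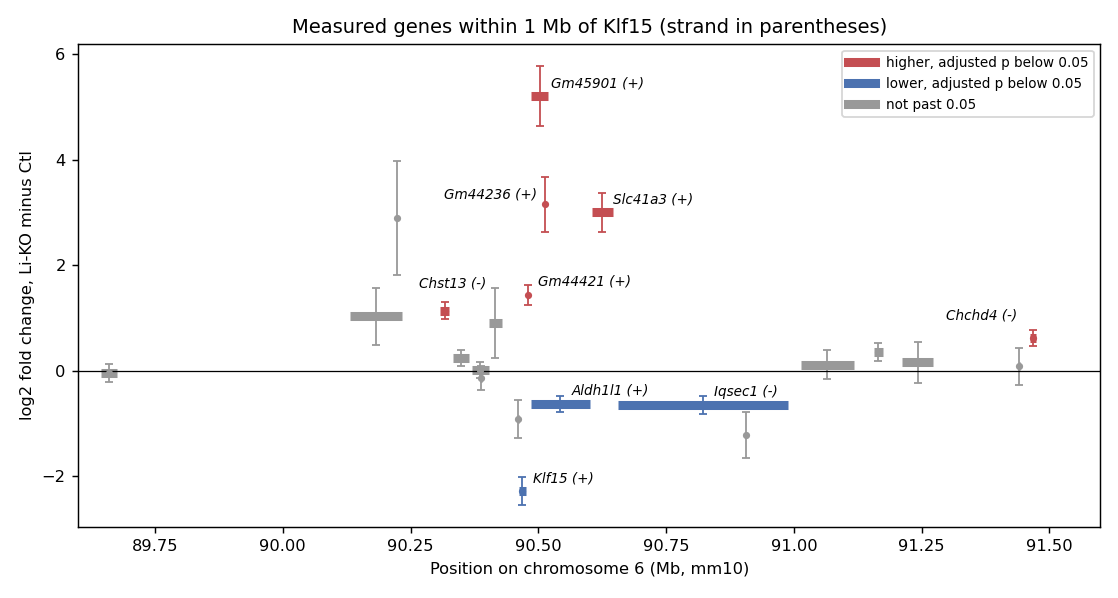
log2 fold change (Li-KO minus Ctl, error bars SE) of Klf15 and the 21 measured genes within 1 Mb of its start, drawn at their positions on chromosome 6 of mm10, with bars for gene bodies. Klf15 lies at -2.28, and Gm44421, Gm45901, Gm44236 and Slc41a3 just downstream lie at 1.44 to 5.21.

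Secreted liver proteins were among the most abundant measured genes. Of the 5 genes of highest mean CPM, Apoa1 was at 7804 ± 1926 CPM in Ctl and 6395 ± 941 CPM in Li-KO, Ttr at 5400 ± 175 and 7959 ± 1673 CPM, Apoa2 at 4870 ± 306 and 7139 ± 1536 CPM and Fga at 5463 ± 1126 and 4889 ± 595.2 CPM. The nuclear RNA Neat1 was at 4086 ± 1634 and 7498 ± 3435 CPM. None of the 5 passed, with adjusted p of 0.110 to 0.651. Alb was skipped in the table.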

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

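Keeping the skipped genes at 0 and removing the genes with a failed FPKM estimate were chosen after the data were seen, and the other alternatives before. The log2 fold change of Klf15 stayed past the threshold in each alternative in which it was looked up, at -2.44 to -1.91 without single libraries. It was not looked up in the test against a fold of 1.5. Counts of higher and lower genes stayed within 1.5 times of 1010 and 976 under other scalings, other filters on counts, limma-voom, the robust fit, both fits of FPKM with a mean of at least 0.5 and both added alternatives. DESeq2 gave 1515 lower genes, limma on log2(FPKM + 1) without a minimum mean 395 higher and 413 lower, and the test against a fold of 1.5, which asks for more, 69 and 138. Without single libraries, which leaves fewer samples, there were 198 to 1102 higher and 234 to 1447 lower genes. The share of higher genes was 47.6% to 54.4% over the scalings against 50.9%, and the median log2 fold change of all genes -0.02 to 0.01. With the replicate block there were 956 higher and 1015 lower genes, 11 lists passed camera and Klf15 was at -2.22. The lists gained with the block were female-biased genes, pericentral genes, nuclear-retained RNAs and cholangiocyte markers. Among the named genes, Arntl, Irf7, Hist2h2be and Hand2 lost their calls with it. Same-numbered libraries did not deviate together (correlations of deviations 0.018, 0.081 and 0.067), so the number is not taken as a pairing, and 4 of the 6 libraries, but neither replicate 0, correlated best with their own number. The number of lists that pass camera, 7, was 0 with an estimated correlation, 3 by fry, 11 without the low-count filter and 6 to 11 without single libraries. Estimated correlations of the 7 lists were 0.136 to 0.443, against the preset 0.01, and a higher correlation raises the p of camera. What moved the other counts was not tested. For the genes within 1 Mb of Klf15, Fisher's exact test gave p = 0.00205, camera p = 0.0112 and camera with an estimated correlation p = 0.134. None of the 109 called genes chosen by the rule for named genes was called with the opposite sign, and 278 values of named genes under an alternative lost their call. In simulated data with 200 changed genes, 2% of changes of 1.5-fold were called. The data gave more called genes, 1986, so this share may not hold for the real comparison.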

Other observations

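Gene families formed from shared symbol stems were grouped and tested after the data were seen. Of 344 families with at least 6 measured genes, 18 passed camera, 15 higher and 3 lower in Li-KO, and 0 passed with an estimated correlation. Mitochondrial ribosomal protein genes rose, 13 of 48 Mrpl genes and 6 of 28 Mrps genes, with 0 falling (camera adjusted p = 3.54e-09 and 0.00019, and 0.969 for both with an estimated correlation). Of 16 Pex genes, which build peroxisomes, 7 rose and 0 fell (adjusted p = 0.00125, and 0.969 with an estimated correlation). Of 349 Zfp zinc finger genes, 30 fell and 7 rose (adjusted p = 0.00191, and 0.969 with an estimated correlation). Annotated gene types differed as well. Of 820 single-exon loci of the TEC class of GENCODE, 54 fell and 2 rose, against 922 and 1008 among the other genes (Fisher's exact p = 5.38e-15 over genes, which are not independent). Of 1027 processed pseudogenes, 76 rose, 8 fell and 943 did not pass (Fisher's exact p = 4.62e-15). Both tests compare the direction of changed genes, not how many changed. Pseudogenes share sequence with their parent genes, and how shared fragments were assigned is not given in the sources used here, so these counts are uncertain.

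Further genes chosen after their values were seen extend the account of Meg3. Rian and Mirg, non-coding RNAs of the same imprinted domain on chromosome 12, rose from 4.89 to 61.1 CPM and from 0.654 to 10.5 CPM (adjusted p = 0.00603 and 0.00775). H19, another imprinted RNA, rose from 0.331 to 2.59 CPM (adjusted p = 0.0375), with 5.51, 1.29 and 0.972 CPM in Li-KO replicates 0, 1 and 2. Its neighbour Igf2 was low in both groups, at 0.485 CPM in Ctl and 0.492 CPM in Li-KO, with a log2 fold change of 0.01 (adjusted p = 0.996). Peg3, a paternally expressed zinc finger gene, fell from 23.1 to 7.77 CPM (adjusted p = 0.00389). The fatty acid transporter Cd36 rose from 43.002 to 216 CPM (adjusted p = 0.00284), and Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, from 79.8 to 186 CPM (adjusted p = 0.0139). Some genes chosen for it differed between Ctl replicate 0 and the other Ctl libraries, which was not tested. Igfbp1 was at 170 CPM in Ctl replicate 0 against 14.6 and 29.6, Lpin1 at 1142 against 287 and 253, and Sds, serine dehydratase, at 733 against 116 and 146. Li-KO libraries differed among themselves in Ntrk2, with 149.9, 34.6 and 1.46 CPM in replicates 0, 1 and 2. Genes skipped in Ctl only had counts in Li-KO that cannot be compared. Mup20 had 88590, 36198 and 18903 counts in Li-KO replicates 0, 1 and 2, Cyp2e1 40477, 93054 and 170088, and Serpina1e 91822, 51706 and 5307.

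The tests in this paragraph on trends and pseudogenes were set before their results were seen. Ribosomal protein and oxidative phosphorylation genes had a median log2 fold change of 0.49 over 145 members. A trend with exonic length and GC content, fitted on the other genes, left a median of 0.41 (95% bootstrap interval 0.35 to 0.49). A trend with intronic length, an indirect measure of the share of unspliced RNA, left 0.43 (0.40 to 0.48). Neither trend accounted for the whole shift. The intervals resample genes, which are correlated within these lists, and do not measure the spread between libraries. The intronic trend explained 1.21% of the variance in the genes it was fitted on. Unspliced RNA that does not follow intronic length therefore stays open. Reads shifted from pseudogenes to their parent genes would lower the pseudogenes, but the 39 measured ribosomal protein pseudogenes had a median of 0.67 (0.48 to 0.88). Because they share sequence with their parent genes, and how shared fragments were assigned is not given, this rise cannot decide the question. A difference in RNA quality between the libraries and an effect of the knockout were not tested and may both contribute.

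Just downstream of Klf15, Gm44421, Gm45901, Gm44236 and Slc41a3 were higher in Li-KO and Aldh1l1 was lower. The tests here were chosen after the rises were seen. Transcription that runs on past the altered Klf15 gene may be a source, since 4 of the 6 raised genes within 1 Mb lie downstream on its strand. However, 2 of them, Gm45901 and Gm44236, overlap Aldh1l1 with uncertain values, and Gm44236 lies within Gm45901, so they are not separate cases. Aldh1l1 itself, on the same strand and ahead of Slc41a3, fell from 1991 to 1293 CPM. A rise of the size seen in Slc41a3, from 3.14 to 25.3 CPM, would be small beside that level. The fall of Aldh1l1 therefore cannot decide for or against such transcription. Chst13 and Chchd4, on the other strand, need another source, and without reads over the gaps between the genes the explanation cannot be told apart from a change of the genes themselves. Flanking variants carried with the altered allele would change genes farther away, and 10.6% of 160 genes from 1 to 10 Mb away changed against 11.99% elsewhere (Fisher's exact p = 0.713), which leaves a shorter segment open.

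The male-biased list was lower in Li-KO by camera, with a median log2 fold change of -0.84 over 27 genes, of which 7 passed, and the tests here were chosen after that was seen. With an estimated correlation its adjusted p was 0.946, and by fry 0.364. A female liver among the Li-KO libraries is argued against by Ddx3y, a Y-linked gene, whose lowest Li-KO level was 67.5% of the Ctl mean, and by Xist at 0.146 CPM or less in Li-KO. Li-KO replicate 2 alone may carry part of the pattern, since without it the median was -0.40 with an interval of -1.12 to 0.05, too wide to decide. Time of day and feeding state were not tested.

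Splits of the 6 libraries into 3 and 3, a test set before its result was seen, number 10, too few for a share under 0.05. The real split gave 1010 higher genes and 976 lower genes, and the highest other split 0 in either direction, so 1 of the 10 splits gave as many in each case. For gene lists, 9 of the 10 splits gave at least the 7 lists of the real split, and the highest other gave 18. Each other split still sets 2 libraries of a group and 1 of the other against the reverse, so a lesser part of the group difference stays in it. Passing camera was therefore not particular to the real grouping, though these counts do not show how much the retained part adds. In the other splits the smallest adjusted p by camera was 1.54e-08 for the male-biased list and 0.0009 for amino acid catabolism. Both were at 0.0155 in the real split, so differences between libraries other than the grouping can give calls of these lists. It was 1.57e-06 for ribosomal proteins, 4.39e-10 for oxidative phosphorylation and 0.000114 for the Kruppel-like factor family, against 8.83e-12, 2.73e-18 and 2.84e-05.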
